A study of Homo sapiens with 12 samples.

How the data were processed

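RNA sequencing of 12 BT-549 libraries was analysed, 1 for each of 4 treatments (CT, NT5M or cdN mRNA, or none) at 6, 12 and 24 h. Per the labels' protocols, cells received 1.25 µg of mRNA with a lipid transfection reagent, RNA was isolated with TRIzol, and libraries were made with a stranded, poly(A)-selecting TruSeq kit. The control was untransfected, and cells given lipid without mRNA were not analysed here. The submitters' processing notes name the genome build hg38 and, without roles, bcl2fastq 2.20.0, FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, Bowtie2 2.3.4.1, StringTie 2.1.3b and DESeq2. The authors deposited 1 table for each of 9 comparisons, and each holds only the genes with a raw p under 0.05. Per the file headers, each deposited table gives raw read counts of both libraries, and TPM by the authors. It also gives log2 values by the authors, which equal the log2 of rpm (reads scaled to 1 fixed effective library total) plus 1 (checked from the values). The authors' signed fold and their raw and adjusted p-values stand beside them, per the file headers, as do the authors' KEGG and GO term tests with their p-values. A further 36 columns of values for these samples were not used.

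The effective size of each library was recovered from its read counts and the authors' log2 values, and was the same in every table that holds the library. The authors' p-values and folds were recomputed from the counts with edgeR's exact test at a fixed biological coefficient of variation of 0.4. All 9068 entries of the 9 tables came within 1%, with a largest relative difference in p of 3.0e-08. The deposited p-values therefore rest on an assumed spread and not on replicates. The smallest absolute fold in the tables was 3.20 to 3.21, above the 2-fold limit in their names. The number of genes tested, 18309 to 18574 by time, was found from the raw and adjusted p-values. Folds here are ratios of reads per effective size, with exact (Clopper-Pearson) 95% intervals for the ratio of 2 counts. The untransfected library held fewer than 10 reads for 22.4% to 25.5% of listed genes. Every listed gene had at least 1 read in both libraries, so genes without reads in either library of a comparison are not covered here. Of 3024 listed genes, 2921 matched RefSeq gene IDs, which gave the positions on GRCh38.p14. Genes that overlap others, copies of histone, ribosomal and 7SL RNA genes and antisense genes are uncertain, since the counting rules are not given in the sources used here.

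Named genes followed a rule set before the data were examined. For each mRNA it took the 5 higher and 5 lower genes with the largest smallest fold over the 3 times, and per time the 3 higher and 3 lower genes with the largest fold. These had to be protein-coding, to have a symbol, an adjusted p under 0.05 in the authors' deposited table and a mean level at or above the lower quartile. It added up to 4 members of each of 20 fixed gene lists with the largest mean fold, NT5C and NT5M, and the 5 pathways or terms with the smallest p among those with 5 to 500 listed genes. CCNA2, FOS, XBP1 and others named with a list come from that part of the rule. For each list with 3 or more listed members, the median fold was ranked among 10000 random lists of the same table, matched in 5 bins of level. Adjustment over a list alone counted every member of the list as tested.

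The planned test with replication over time used edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with treatment and time as factors on the 139 genes with counts in all 12 samples, with the effective sizes as library sizes. The fit had 6 residual degrees of freedom and a common biological coefficient of variation of 0.331. Its p-values measure the spread of an effect over the times, and nothing in the labels says whether the times were separate cultures. Each SE was computed back from the test, as the absolute log2 difference over the square root of the F statistic. It was not estimated separately. Overlaps were set beside those of independent lists and of 10 simulated sets of unchanged libraries that share the control, with levels drawn from the listed genes. Alternatives were an adjusted p, a 4-fold limit, a level filter, a pseudocount of 1, coding genes, limma 3.58.1, left-out times and, added later, TPM scales, a wider spread and other feature sets. Steps were tested on simulated data. In the 139-gene fit of CT against untransfected libraries, 8 of 30 simulated 2-fold and 30 of 30 4-fold changes were called, and 0 of 79 unchanged genes. With 1 library against 1 in a step of 5000 genes, 172 of 200 8-fold changes and 167 of 4800 unchanged genes had a p under 0.05. For CT at 12 h the interval held the true fold for 96.6% of 1975 genes, and 8% of random lists lay above the 95th percentile. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.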

Results

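The transcriptome of BT-549 cells, a human triple-negative breast cancer line, was measured by stranded mRNA sequencing after transfection with 1 of 3 synthetic mRNAs. One mRNA was named cdN, after the cytosolic 5'(3')-deoxyribonucleotidase encoded by NT5C, and another NT5M, after its mitochondrial counterpart. The remaining one was named CT, and what it encodes is not given in the sources used here. Cells received 1.25 µg of mRNA in a cationic lipid reagent, or no transfection, and were harvested after 6, 12 or 24 h. These 4 treatments and 3 times gave 12 groups with 1 library each. The effective library sizes of the untransfected cells were 57.0, 69.1 and 74.6 M reads at 6, 12 and 24 h. Those with CT mRNA were 34.9, 41.5 and 23.4 M, with NT5M mRNA 52.1, 45.8 and 53.2 M and with cdN mRNA 48.6, 50.3 and 54.8 M. The series title sets CT mRNA against control cells, so the 9 comparisons of a transfected with the untransfected library of the same time came first. Only genes that the authors listed in a comparison were measured here, and a gene not listed is not shown to be unchanged. With 1 library per group, no difference at a single time has a replicate check. Each fold is followed by its 95% counting interval, which covers counting error only.

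The transfected mRNAs were present in their own libraries. NT5C (gene ID 30833, chromosome 17, 75130228 to 75131742, GRCh38.p14) was 17025-fold (15814 to 18354) higher in the cdN than in the untransfected library at 6 h, 16469-fold (15436 to 17591) at 12 h and 14016-fold (13144 to 14961) at 24 h. It took 36.3%, 37.9% and 33.4% of the summed transcript abundance (TPM) there. NT5M (gene ID 56953, chromosome 17, 17303373 to 17347663) was 46766-fold (40716 to 53990.2), 42108-fold (37390 to 47597) and 71498-fold (62435 to 82275) higher in the NT5M libraries at the 3 times. It took 21.1%, 21.3% and 24.97% of TPM. Smaller excesses appeared in libraries that had not received the mRNA in question. NT5M was 13.1-fold (11.3 to 15.3) higher with CT mRNA at 6 h and 10.7-fold (9.15 to 12.5) at 24 h, and NT5C was 8.74-fold (8.08 to 9.46) higher with NT5M mRNA at 6 h (adjusted p = 0.13 in the authors' deposited table) and 17.2-fold (16.1 to 18.5) at 12 h. Where these reads came from was not tested, so they are not shown to be expression in those cells. Measured in TPM, which count the transfected mRNA, the median fold of listed genes shifted on the log2 scale. The shift lay between -0.06 (CT mRNA, 24 h) and -0.79 (cdN mRNA, 12 h). No listed gene changed sign, which says little, since the smallest absolute fold in the lists was 3.20.

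With CT mRNA at 6 h the fold of IFNB1 (gene ID 3456, chromosome 9, 21077104 to 21077942), which encodes interferon beta, led the named genes. It was 15531-fold (5314 to 75314) higher than in untransfected cells. RAET1L, a ligand of the activating receptor NKG2D, was 785-fold (381 to 1955) higher, and CH25H, the cholesterol 25-hydroxylase, 680.4-fold (445 to 1099.7). The transcription factor gene EGR4 was 599.9-fold (392 to 969.7) higher and the T cell chemokine gene CXCL11 522-fold (284 to 1089.7). IFIT2 (gene ID 3433, chromosome 10, 89302046 to 89309271), an interferon-stimulated gene, went from 3938 to 336079 reads and was 139-fold (135 to 144) higher. The authors listed 977 of 18500 genes, of which 928 (94.98%) were higher and 49 lower. Among the lower genes that met the naming rule, the readthrough gene TMEM189-UBE2V1 led, 24.0-fold (11.5 to 60.1) lower. Immediate early genes were higher for 19 of 25 members, among them EGR3 at 434-fold (350.0 to 544) and EGR1 at 139-fold (133 to 145). PPP1R15A, which restores translation after stress, was 107-fold (103 to 111) higher, and the NF-kB inhibitor gene TNFAIP3 96.6-fold (92.0 to 101.5). The proapoptotic genes BBC3 and PMAIP1 were 52.3-fold (44.8 to 61.5) and 45.1-fold (42.7 to 47.7) higher. The adjusted p of the authors' deposited table was under 0.05 for 295 genes, 291 of them higher. Simulated unchanged libraries with the spread the authors assumed listed a mean of 686 genes at a raw p under 0.05, where a rate of 5% would give 925.

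At 12 h CT mRNA gave more listed genes and, for many response genes, larger folds. IFNB1 was 8450-fold (4288 to 19574) higher, EGR4 3288-fold (1595 to 8178), CXCL11 1939.6-fold (757 to 7122) and RAET1L 1823-fold (781 to 5618). IFIT2 was 208-fold (201 to 215) higher, and OASL, which enhances sensing of viral RNA, 56.6-fold (54.7 to 58.6). CD274 (gene ID 29126, chromosome 9, 5450542 to 5470554), which encodes the checkpoint ligand PD-L1, was 65.8-fold (57.1 to 76.2) higher. Interferon-stimulated genes were higher for 40 of 61 members, and interferons, cytokines and chemokines for 21 of 27, with a median fold of 30.4. The authors listed 1657 of 18574 genes, 1531 higher and 126 lower. Long noncoding RNAs made up 406 of the higher genes. With a pseudocount of 1 rpm the log2 fold of IFNB1 was 9.78 in place of 13.04, and that of CXCL10 5.72 in place of 8.45. PIGY, which takes part in the synthesis of membrane anchors, was 9.05-fold (6.33 to 13.4) lower. The adjusted p of the authors' deposited table was under 0.05 for 600 genes.

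By 24 h the folds of most leading genes with CT mRNA were smaller, and more genes were lower. IFNB1 was 927-fold (617 to 1464) higher and IFIT2 34.9-fold (34.2 to 35.6). IFNL1, which encodes interferon lambda 1, was 2020.0-fold (1224 to 3611) higher, and TRAF1, an adaptor of TNF receptors, 52.0-fold (47.3 to 57.4). CXCL11 was 4614-fold (827 to 182368) higher, a ratio that rests on 1 control read. KIF20A, a mitotic kinesin gene, was 6.04-fold (5.57 to 6.57) lower and CCNA2, which encodes cyclin A2, 3.83-fold (3.51 to 4.198) lower. COL3A1, a fibrillar collagen gene, was 4.71-fold (4.52 to 4.91) lower. These 3 genes failed correction, with an adjusted p of 0.086, 0.34 and 0.19 in the authors' deposited table. CD302, a lectin receptor gene, was 33.3-fold (11.3 to 162) lower and PLEKHS1 26.1-fold (7.11 to 217) lower, and the readthrough gene ZNF559-ZNF177 46.8-fold (8.28 to 1862), while ZNF177, which it spans, had a log2 fold of 3.13. Of 18309 genes tested, the authors listed 1752, and 1424 (81.3%) were higher and 328 lower. Under an adjusted p of 0.05 in the authors' deposited table, 543 were higher and 37 lower.

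**Figure D1:**
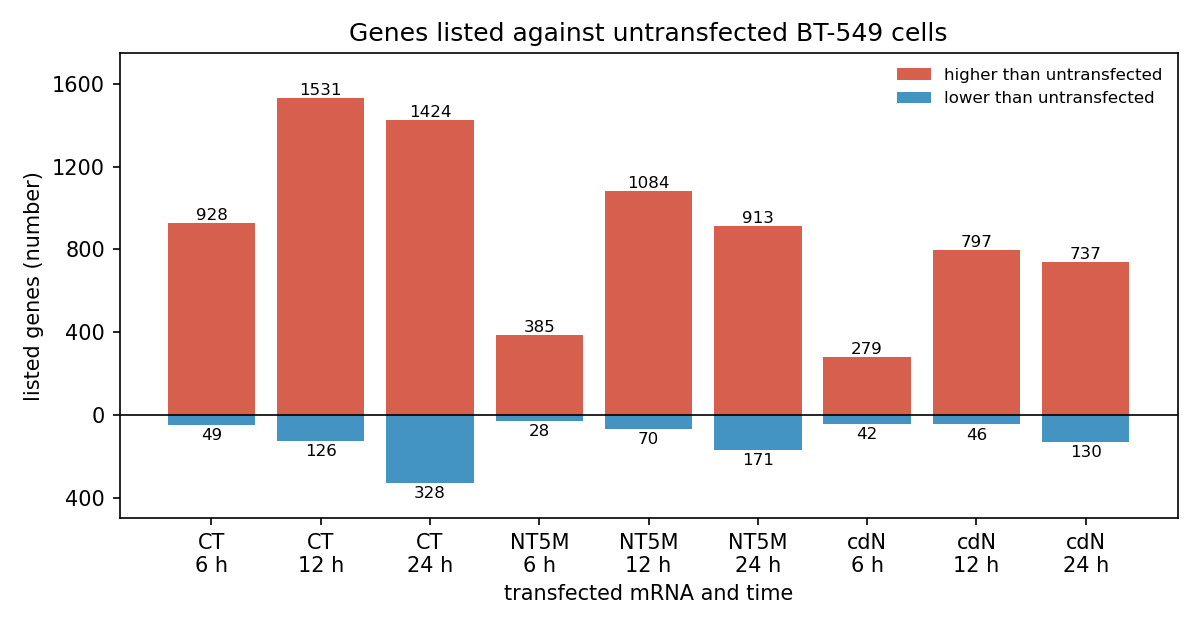
Number of genes listed in each of the 9 comparisons with the untransfected library of the same time, by transfected mRNA and time in hours. Bars above 0 count genes higher and bars below 0 genes lower in the transfected library. CT mRNA had 928, 1531 and 1424 higher genes at 6, 12 and 24 h, more than NT5M mRNA or cdN mRNA at each time.

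NT5M mRNA at 6 h gave large folds of IFNB1 and other genes named with CT mRNA. Besides NT5M itself, IFNB1 was 2445-fold (836 to 11858) higher, CH25H 149.7-fold (97.7 to 242) and RAET1L 127-fold (61.3 to 317). CXCL10, a chemokine gene induced by interferon, was 148-fold (80.1 to 309) higher and IFIT2 58.0-fold (56.2 to 59.8). The stress response genes PPP1R15A and ATF3 were 22.6-fold (21.8 to 23.4) and 18.3-fold (17.0 to 19.6) higher. Of 18500 genes tested, the authors listed 413, and 385 were higher and 28 lower. The lower genes that met the naming rule were led by the readthrough genes JMJD7-PLA2G4B at 39.1-fold (17.7 to 108), ABCF2-H2BE1 at 24.9-fold (14.4 to 47.2) and FAM47E-STBD1 at 13.8-fold (8.34 to 24.6). PLA2G4B, which the first spans, had a log2 fold of 5.24. The last 2 were higher at 12 h, 9.93-fold (6.32 to 16.3) and 13.8-fold (10.1 to 19.3). An adjusted p under 0.05 in the authors' deposited table was given for 56 genes.

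With NT5M mRNA at 12 h, after NT5M itself, IFNB1 was 1801-fold (913 to 4172) higher, EGR4 904-fold (438 to 2249) and CXCL11 610.0-fold (238 to 2241). BATF2, an interferon-stimulated transcription factor gene, was 30.2-fold (26.8 to 34.1) higher and CD274 38.3-fold (33.2 to 44.4). XBP1, a regulator of the unfolded protein response, was 7.12-fold (6.88 to 7.37) higher (adjusted p = 0.075 in the authors' deposited table). ADORA2A, which encodes an adenosine receptor, was 21.5-fold (13.6 to 35.9) lower, while the readthrough gene SPECC1L-ADORA2A that spans it had a log2 fold of 6.53. The list held 1154 of 18574 genes, 1084 higher and 70 lower, and 320 had an adjusted p under 0.05 in the authors' deposited table. Simulated unchanged libraries listed 726.

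After 24 h with NT5M mRNA, IFNL1 was 500.1-fold (303 to 894) higher, TRAF1 46.7-fold (42.4 to 51.4) and IFNB1 187-fold (124 to 295). MMP10, a stromelysin gene, was 30.1-fold (13.5 to 83.6) higher. KIF20A, named with the G2 and mitosis list, was 4.196-fold (4.001 to 4.40) lower at a raw p under 0.05 but failed correction (adjusted p = 0.45 in the authors' deposited table). TMEM37, SOHLH2 and the readthrough gene COMMD3-BMI1 were 18.6-fold (7.03 to 69.4), 12.9-fold (6.11 to 32.9) and 25.1-fold (15.1 to 45.2) lower. Of 18309 genes tested, the authors listed 1084, and 913 were higher and 171 lower, and 252 had an adjusted p under 0.05 in the authors' deposited table. In simulated unchanged libraries 722 were listed.

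cdN mRNA at 6 h gave the shortest list. After NT5C, IFNB1 was 1472-fold (503 to 7141) higher, CXCL10 108-fold (58.3 to 225) and CH25H 100.9-fold (65.8 to 163). IFIT2 was 43.8-fold (42.5 to 45.2) higher, and the immediate early genes EGR1 and FOS 39.9-fold (38.3 to 41.7) and 36.8-fold (32.5 to 41.9). GPRASP2, a receptor sorting gene, was 35.6-fold (16.1 to 97.9) lower and SLCO5A1, of the organic anion transporter family, 14.6-fold (10.02 to 22.0). Of 18500 genes tested, the authors listed 321, and 279 were higher and 42 lower, and 40 had an adjusted p under 0.05 in the authors' deposited table. Simulated unchanged libraries with the assumed spread listed 722 for cdN and 708 for NT5M mRNA at 6 h, more than the authors did for either.

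At 12 h with cdN mRNA, IFNB1 was 1261-fold (639.8 to 2922) higher, EGR4 486-fold (236 to 1210.3) and CXCL11 349-fold (136 to 1283). OASL was 23.8-fold (23.0 to 24.7) higher, TNFAIP3 47.1-fold (44.5 to 49.9) and CD274 27.4-fold (23.8 to 31.8). The p53 target gene GADD45A was 11.03-fold (10.6 to 11.5) higher (adjusted p = 0.02 in the authors' deposited table), and AEN, named with the same list, was 3.87-fold (3.66 to 4.104) higher but failed that correction (adjusted p = 0.72 in the authors' deposited table). SOWAHD was 4.26-fold (3.12 to 5.94) lower, with an adjusted p of 0.65 in the authors' deposited table, and is named for its fold at 24 h. Of 18574 genes tested, the authors listed 843, and 797 were higher and 46 lower, and 212 had an adjusted p under 0.05 in the authors' deposited table. The simulated unchanged library listed 710.4 and a rate of 5% would give 929, so the number listed lay between them.

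After 24 h with cdN mRNA, IFNL1 was 316-fold (191 to 566) higher, TRAF1 33.3-fold (30.3 to 36.7) and IFNB1 163-fold (109 to 258). The matrix metalloproteinase genes MMP10 and MMP3 were 35.6-fold (16.0 to 98.5) and 11.03-fold (8.90 to 13.8) higher. SOWAHD was 17.99-fold (12.4 to 27.1) lower, GPRASP2, named for 6 h, 7.79-fold (5.50 to 11.4) (adjusted p = 0.12 in the authors' deposited table) and the readthrough gene GET1-SH3BGR 46.5-fold (15.7 to 228). Of 18309 genes tested, the authors listed 867, and 737 were higher and 130 lower, and 149 had an adjusted p under 0.05 in the authors' deposited table. It lay between the 702 of simulated unchanged libraries and the 915 of a rate of 5% as well.

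**Figure D2:**
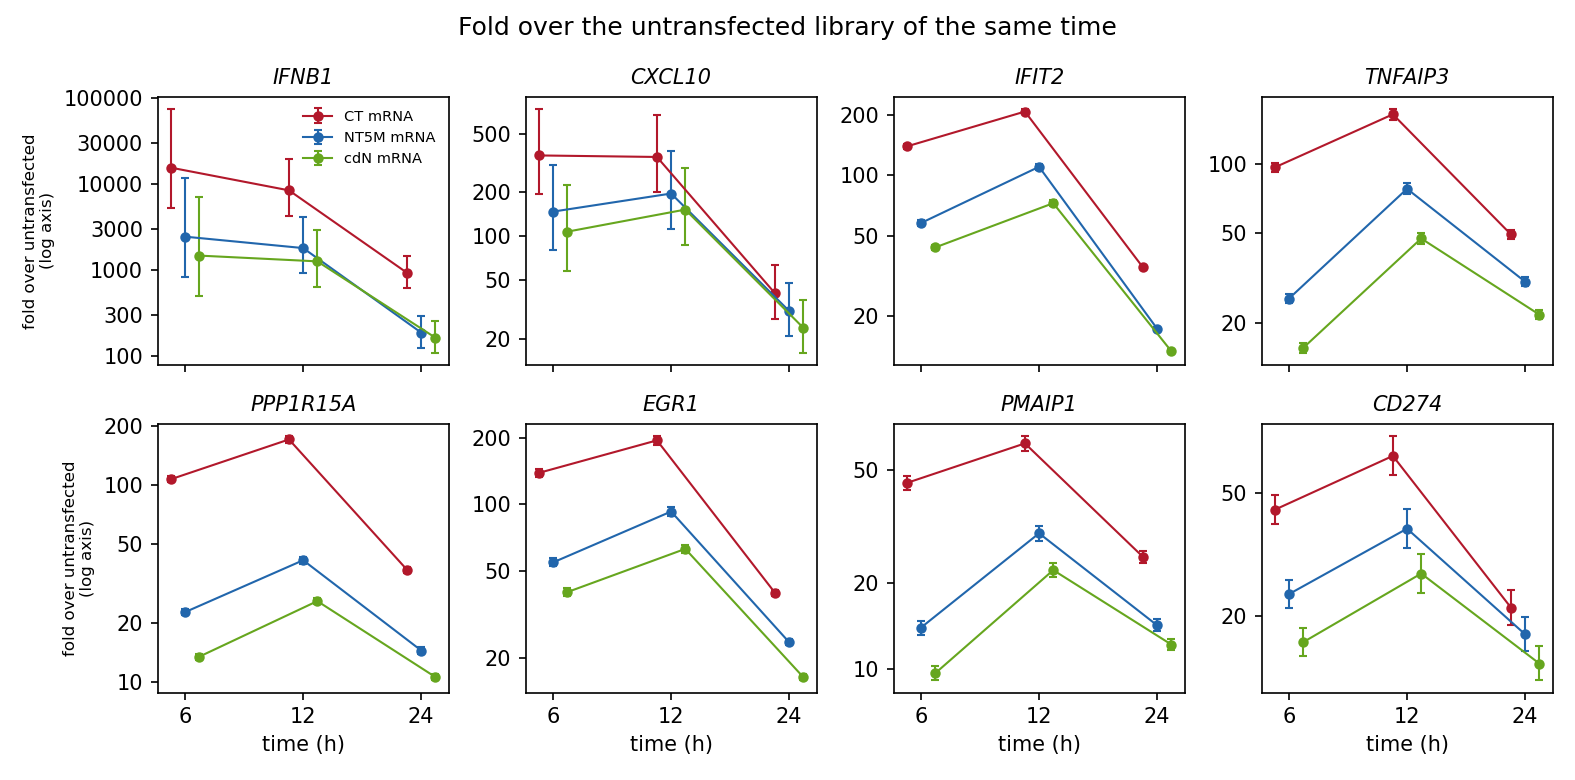
Fold over the untransfected library of the same time (log axis) against time in hours for 8 genes. Points are single libraries with CT, NT5M or cdN mRNA, bars are 95% counting intervals, and lines join the times of 1 mRNA. The CT point lies above the NT5M and cdN points for each gene at each time.

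Replication was available only over the times. Each of the 139 genes listed in all 9 tables could be followed in the 12 libraries, and was tested with edgeR's quasi-likelihood test with time as a block. All 139 rose with CT mRNA, by a median of 4.44 on the log2 scale, with NT5M mRNA (3.52) and with cdN mRNA (3.12). The largest Benjamini-Hochberg adjusted p of edgeR's test was 3.4e-05, 6.2e-05 and 1.0e-04 in turn. IFNB1 rose by 11.76 ± 0.77 (SE) with CT mRNA, 9.34 ± 0.71 (SE) with NT5M mRNA and 8.83 ± 0.70 (SE) with cdN mRNA. CD274 rose by 5.29 ± 0.41 (SE), 4.60 ± 0.39 (SE) and 4.16 ± 0.38 (SE), and ZBP1, a sensor of Z-form nucleic acids, by 5.05 ± 0.38 (SE), 4.59 ± 0.38 (SE) and 4.17 ± 0.37 (SE). Among these genes were 14 interferon-stimulated genes, 12 interferons, cytokines and chemokines and 11 immediate early genes. They were chosen because they passed in all 9 comparisons, so their higher level is not independent evidence.

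CT mRNA gave larger effects than either nucleotidase mRNA on most of these genes. PPP1R15A rose by 2.57 ± 0.44 (SE) on the log2 scale more with CT than with cdN mRNA (edgeR adjusted p = 2.3e-04) and by 1.94 ± 0.43 (SE) more than with NT5M mRNA (edgeR adjusted p = 0.0041), with the larger fold at 3 of 3 times. For IFNB1 the differences were 2.93 ± 0.51 (SE) and 2.42 ± 0.50 (SE), and for EGR4 2.92 ± 0.51 (SE) and 2.03 ± 0.49 (SE). BBC3, a p53 target that promotes apoptosis, differed by 2.19 ± 0.45 (SE) and 1.64 ± 0.44 (SE). IFIT2 differed by 1.54 ± 0.52 (SE) from cdN mRNA (edgeR adjusted p = 0.014) but missed the threshold against NT5M mRNA at 1.07 ± 0.51 (SE) (edgeR adjusted p = 0.086). MLKL, the effector of necroptosis, differed by -0.09 ± 0.39 (SE) and -0.19 ± 0.39 (SE) and BATF2 by 0.18 ± 0.36 (SE) and -0.05 ± 0.36 (SE), neither past the threshold. By edgeR's test 107 of 139 genes were higher with CT than with cdN mRNA and 73 than with NT5M mRNA, and 0 were lower. At a raw p under 0.05 the counts were 108 and 84. Between NT5M and cdN mRNA edgeR called 0 genes, with 3 at a raw p under 0.05, although 137 of 139 lay higher with NT5M mRNA, by a median of 0.41. Fitting only the libraries with those 2 mRNAs called 105. Without the 6 h libraries the CT counts were 56 against cdN and 12 against NT5M mRNA, and without the 12 h libraries 38 against NT5M mRNA.

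Among the genes higher with all 3 mRNAs, CT mRNA gave the largest fold for 93.8% at 6 h, 84.8% at 12 h and 82.9% at 24 h. These genes numbered 227, 719 and 595 at 6, 12 and 24 h. The median ratio of the CT to the cdN fold was 2.86, 1.91 and 1.90, that of CT to NT5M 2.35, 1.48 and 1.53, and that of NT5M to cdN 1.27, 1.29 and 1.24. The order CT, NT5M, cdN held for 84.1%, 75.1% and 73.3% of them. EGR4 at 6 h, for example, was 599.9-fold higher with CT mRNA, 77.9-fold with NT5M mRNA and 39.2-fold with cdN mRNA. TNFSF10, which encodes the death ligand TRAIL, ran the other way at 6 h, with 10.1-fold (5.93 to 18.4), 13.4-fold (8.05 to 23.9) and 15.2-fold (9.16 to 27.1), intervals that overlap. The 66 genes lower with all 3 mRNAs at 24 h, KIF20A among them, had a median log2 fold of -2.69 with CT, -2.16 with NT5M and -2.05 with cdN mRNA.

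**Figure D3:**
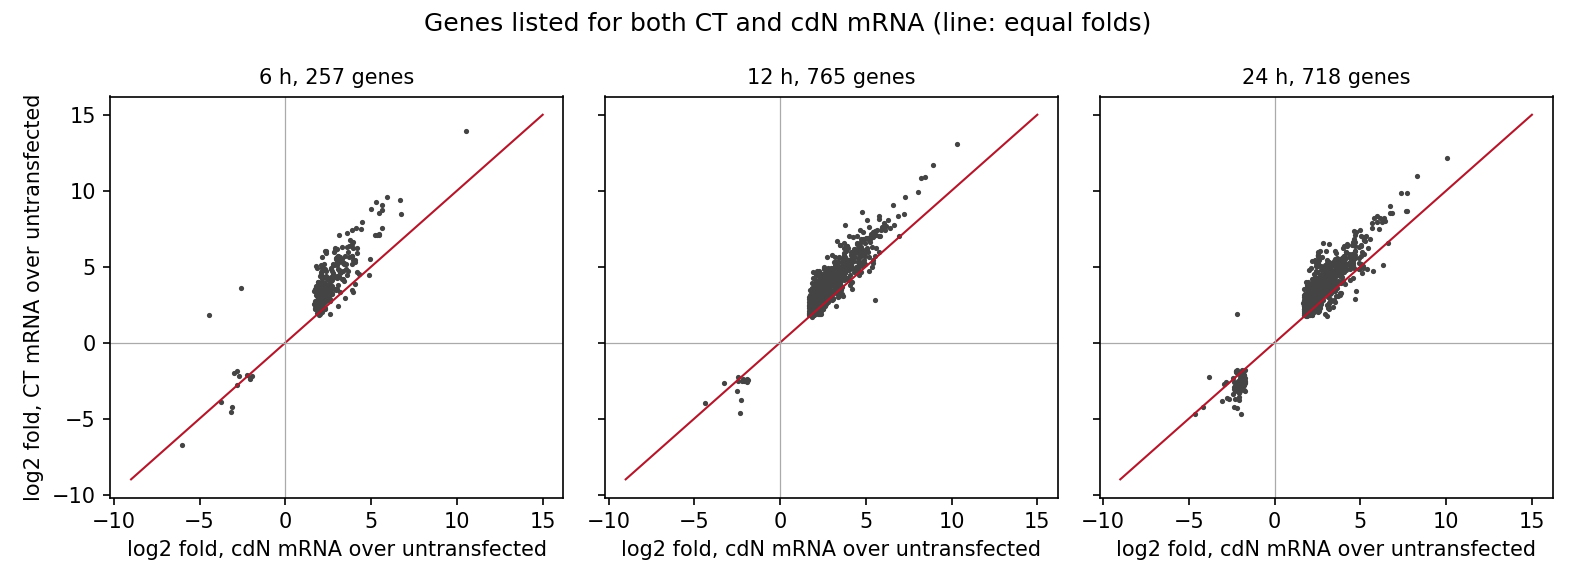
log2 fold over untransfected with CT mRNA (vertical) against that with cdN mRNA (horizontal) for genes listed with both, at 6, 12 and 24 h. Each point is 1 gene and the line marks equal folds. Most higher genes lie above the line, with median differences of 1.51, 0.93 and 0.92 on the log2 scale among genes higher with all 3 mRNAs.

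The lists for the 3 mRNAs overlapped. The 727 genes listed with 1 sign for all 3 at 12 h included IFNB1, IFIT2, TNFAIP3 and PPP1R15A, and 589 genes were listed for CT mRNA alone. At 6 h these counts were 233 and 591, and at 24 h 661 and 780. Of the 797 genes higher with cdN mRNA at 12 h, 752 were higher with CT mRNA, where independent lists would share 65.7. Simulated unchanged libraries against the same control shared 92.6 higher genes, so part of the excess may come from the shared control. Of the 1084 genes higher with NT5M mRNA at 12 h, 1002 were higher with CT mRNA, against 89.4 for independent and 94.8 for simulated lists. At 6 and 24 h CT and cdN mRNA shared 243 and 640 higher genes, against 13.995 and 57.3 for independent and 94 and 86.9 for simulated lists. Between NT5M and cdN mRNA 732 higher genes were shared at 12 h, against 46.5 and 94.7. The simulated lists held 318 to 359 higher genes and the real ones 279 to 1531. Simulated shared counts of higher genes therefore cannot be set directly against those of the real or independent lists. The lower genes shared at 6 h numbered 7 between CT and NT5M mRNA, 12 between CT and cdN and 10 between NT5M and cdN mRNA, and at 12 h 26, 13 and 13. As a share of the list named last in each pair they made up 23.8% to 37.1%, against 8.95% to 10.495% in the simulated lists, which were longer. Independent lists would share 0.0636 to 0.475 genes. These real lists held 28 to 70 lower genes and the simulated ones 367 to 375. At 24 h they numbered 105 between CT and NT5M mRNA, 77 between CT and cdN and 83 between NT5M and cdN mRNA. Independent lists would share 3.06, 2.33 and 1.21. The shares were 59.2% to 63.8%, against 9.72% to 10.3% in the simulated lists.

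Over time, 527 genes were listed with 1 sign at all 3 times of CT mRNA, 526 of them higher. For 355 the fold was largest at 12 h, as for IFIT2, TNFAIP3 and EGR1, for 62 at 6 h, as for IFNB1 and BTG2, and for 110 at 24 h, as for TRAF1 and GADD45A. The counting intervals of IFNB1 at 6 and 12 h, given above, overlap, so the order of those times is uncertain for it. GADD45A, a growth arrest gene, was 6.11-fold (5.88 to 6.34), 13.1-fold (12.6 to 13.7) and 19.6-fold (18.8 to 20.5) higher at the 3 times, and TRAF1 13.1, 33.3 and 52.0-fold. The 6 h value of GADD45A failed correction (adjusted p = 0.14 in the authors' deposited table). Genes listed at 1 time alone numbered 178 at 6 h, 513 at 12 h and 800 at 24 h, and 285 of the last were lower. With NT5M mRNA 226 genes and with cdN mRNA 152 were listed with 1 sign at all 3 times, 226 and 150 of them higher. The order of times was not tested, since each time had 1 library.

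Among the gene lists fixed before the data were examined, the members of the antiviral, inflammatory and immediate early lists that were listed were all higher. Of all listed genes, 81.3% to 94.98% were higher in the 9 comparisons, so a shared direction alone says little. Of 61 interferon-stimulated genes, 26, 40 and 17 with CT mRNA, 22, 34 and 15 with NT5M mRNA and 21, 33 and 16 with cdN mRNA were listed at 6, 12 and 24 h. Of 27 interferons, cytokines and chemokines, 18, 21 and 19 with CT mRNA, 12, 18 and 18 with NT5M mRNA and 12, 17 and 18 with cdN mRNA were. At 12 h their medians lay at the 100th, 100th and 99.99th percentile of 10000 random lists of like level from the CT, NT5M and cdN tables, which describes these libraries and is not a test. For the interferon-stimulated genes the percentiles were 95.8, 100 and 99.2 at 12 h, 98.1, 79.6 and 70.2 at 6 h and 96.6, 72.3 and 28.9 at 24 h. For the cytokine list they were 99.9, 95.9 and 82.6 at 6 h. Of 16 NF-kB targets, 9, 15 and 13 with CT mRNA, 7, 14 and 9 with NT5M mRNA and 6, 11 and 7 with cdN mRNA were listed, with BIRC3, an inhibitor of apoptosis, 19.5-fold (18.3 to 20.9) higher with CT mRNA at 12 h. Their percentiles ran from 50.5 (cdN mRNA, 6 h) to 97.4 (CT mRNA, 12 h), and those of the immediate early genes from 89.4 (CT mRNA, 24 h) to 100 (CT mRNA, 6 and 12 h). Of 25 immediate early genes, 19, 20 and 19 with CT mRNA, 18, 19 and 17 with NT5M mRNA and 16, 19 and 14 with cdN mRNA were. Fewer held an adjusted p under 0.05 over all genes in the authors' deposited table. For the interferon-stimulated genes these were 16, 20 and 7 with CT, 5, 18 and 4 with NT5M and 4, 15 and 3 with cdN mRNA at 6, 12 and 24 h (adjusted over the list alone, 22, 33 and 14 with CT, 19, 31 and 5 with NT5M and 9, 27 and 5 with cdN mRNA). For the cytokine list the authors' deposited table gave 12, 18 and 18 with CT, 4, 14 and 15 with NT5M and 4, 13 and 14 with cdN mRNA (list alone, 18, 21 and 18 with CT, 12, 17 and 18 with NT5M and 9, 16 and 18 with cdN mRNA). For the NF-kB targets the authors' deposited table gave 7, 9 and 4 with CT, 1, 6 and 4 with NT5M and 1, 4 and 3 with cdN mRNA (list alone, 9, 15 and 12 with CT, 7, 13 and 7 with NT5M and 3, 9 and 4 with cdN mRNA). For the immediate early genes the authors' deposited table gave 14, 16 and 8 with CT, 7, 13 and 5 with NT5M and 5, 11 and 4 with cdN mRNA (list alone, 19, 20 and 18 with CT, 16, 19 and 13 with NT5M and 16, 19 and 11 with cdN mRNA). Of 19 antigen presentation genes, 2, 4 and 2 with CT mRNA, 3, 5 and 1 with NT5M mRNA and 3, 4 and 1 with cdN mRNA were listed, with ERAP2, an aminopeptidase gene, 7.61-fold (6.78 to 8.56) higher with CT mRNA at 12 h. Those with an adjusted p under 0.05 over all genes in the authors' deposited table numbered 1, 2 and 1 with CT, 1, 1 and 1 with NT5M and 1, 1 and 1 with cdN mRNA (list alone, 1, 3 and 1 with CT, 1, 2 and 1 with NT5M and 1, 1 and 1 with cdN mRNA). Where 3 or more antigen presentation genes were listed, their percentiles ran from 19.1 (cdN mRNA, 6 h) to 49.4 (CT mRNA, 12 h).

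Stress, p53 and death genes were listed in part. Percentiles among random lists ran from 31.95 (cdN mRNA, 6 h) to 98.9 (CT mRNA, 24 h) for the stress genes. For the p53 targets they ran from 39.0 (cdN mRNA, 12 h) to 97.8 (CT mRNA, 6 h). For the apoptosis genes they ran from 27.6 (CT mRNA, 6 h) to 96.6 (CT mRNA, 24 h), and for the histones from 1.66 (CT mRNA, 6 h) to 80.0 (CT mRNA, 24 h). Most listed genes of any kind were higher. Of 28 genes of the endoplasmic reticulum and integrated stress response, 6, 10 and 7 with CT mRNA, 4, 8 and 6 with NT5M mRNA and 5, 9 and 6 with cdN mRNA were listed at 6, 12 and 24 h, all higher. Of 26 p53 targets, 4, 7 and 6 with CT mRNA, 4, 6 and 6 with NT5M mRNA and 3, 7 and 6 with cdN mRNA were, all higher, and of 30 apoptosis genes 7, 7 and 4 with CT mRNA, 3, 7 and 4 with NT5M mRNA and 3, 6 and 4 with cdN mRNA, all higher. HRK, a BH3-only gene, was 16.9-fold (11.3 to 26.1) higher with CT mRNA at 24 h. An adjusted p under 0.05 over all genes in the authors' deposited table held for 2, 5 and 4 with CT, 2, 2 and 2 with NT5M and 2, 2 and 2 with cdN mRNA of the stress genes (list alone, 5, 5 and 6 with CT, 2, 5 and 4 with NT5M and 2, 5 and 3 with cdN mRNA). It held in the authors' deposited table for 3, 4 and 4 with CT, 1, 3 and 2 with NT5M and 1, 3 and 2 with cdN mRNA of the p53 targets (list alone, 4, 6 and 6 with CT, 2, 5 and 5 with NT5M and 2, 3 and 2 with cdN mRNA). It held in the authors' deposited table for 3, 3 and 3 with CT, 2, 3 and 3 with NT5M and 1, 3 and 2 with cdN mRNA of the apoptosis genes (list alone, 5, 6 and 3 with CT, 3, 3 and 3 with NT5M and 3, 3 and 2 with cdN mRNA). Of 19 replication-dependent histones, whose mRNAs lack poly(A) tails, 10, 15 and 11 with CT mRNA, 2, 7 and 5 with NT5M mRNA and 1, 7 and 3 with cdN mRNA were listed, all higher. H4C14 was 22.8-fold (17.4 to 30.2) higher with CT mRNA at 12 h. Histone genes with an adjusted p under 0.05 over all genes in the authors' deposited table numbered 1, 6 and 5 with CT, 0, 1 and 0 with NT5M and 0, 1 and 0 with cdN mRNA (list alone, 4, 15 and 10 with CT, 1, 1 and 1 with NT5M and 0, 1 and 0 with cdN mRNA). Of the other RNAs without poly(A) tails, chosen after their values were seen, RPPH1 and RN7SK were lower with CT mRNA at 6 h and higher at 24 h, when 23 of 24 listed ribosomal RNA copies were higher. The heat shock list gave 1 listed gene of 14, DNAJB4, 3.50-fold (3.37 to 3.64) higher with CT mRNA at 6 h (adjusted p = 0.76 in the authors' deposited table). An adjusted p under 0.05 held for 0 heat shock genes over all genes in the authors' deposited table and for 0 adjusted over the list alone.

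Genes of proliferation and energy metabolism were rarely listed. None of 42 S phase genes, 13 mitochondrially encoded genes or 24 nuclear genes of oxidative phosphorylation passed the authors' threshold in any of the 9 comparisons. Of 32 G2 and mitosis genes, 2, 1 and 1 were lower at 24 h with CT, NT5M and cdN mRNA, and none was listed earlier. Of 42 nucleotide metabolism genes, 2, 0 and 2 with CT mRNA, 2, 2 and 2 with NT5M mRNA and 1, 1 and 2 with cdN mRNA were listed. These were NT5C, NT5M, whose reads with CT mRNA are of untested origin, and SLC28A3, a nucleoside transporter gene, at up to 9.14-fold (5.75 to 15.2) with cdN mRNA at 24 h (adjusted p = 0.093 in the authors' deposited table). Of 22 hypoxia and glycolysis genes, 2, 3 and 2 with CT mRNA, 0, 2 and 2 with NT5M mRNA and 0, 2 and 1 with cdN mRNA were higher, with ANGPTL4, a lipase inhibitor gene, 12.2-fold (11.5 to 12.9) with CT mRNA at 12 h. Of 25 matrix and TGF-beta genes, 1, 3 and 7 with CT mRNA, 0, 2 and 4 with NT5M mRNA and 0, 2 and 3 with cdN mRNA were listed, and at 24 h with CT mRNA 3 were higher and 4 lower. Of 21 mesenchymal and epithelial genes, 1, 3 and 6 with CT mRNA, 0, 3 and 4 with NT5M mRNA and 0, 2 and 2 with cdN mRNA were. With CT mRNA at 24 h ESRP1, an epithelial splicing regulator, was 35.0-fold (12.7 to 134) higher and CDH1, which encodes E-cadherin, 4.41-fold (2.89 to 7.06) lower (adjusted p = 0.30 in the authors' deposited table). Of 22 markers of other cell types, 1, 3 and 3 with CT mRNA, 0, 3 and 3 with NT5M mRNA and 0, 2 and 2 with cdN mRNA were listed, such as CHGA, a neuroendocrine marker, 13.5-fold (7.76 to 24.98) with CT mRNA at 24 h from 16 control reads. At 24 h with CT mRNA, adjusted p under 0.05 over all genes in the authors' deposited table held for 0, 1, 1, 1, 1 and 2 members of the G2 and mitosis, nucleotide, hypoxia, matrix, mesenchymal and epithelial, and other cell type lists in turn. Adjusted over the list alone, the counts were 0, 1, 1, 2, 1 and 3. In the other 8 comparisons the authors' deposited table gave 0 for the G2 and mitosis list and at most 2 for each other list (list alone, 0 and at most 3). Where 3 or more members were listed, percentiles ran from 2.19 (CT mRNA, 24 h) to 90.3 (cdN mRNA, 24 h) for the matrix list. For the mesenchymal and epithelial list they ran from 10.6 (CT mRNA, 24 h) to 57.7 (CT mRNA, 12 h).

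The KEGG pathway of TNF signaling held 35, 42 and 34 listed genes with CT mRNA at 6, 12 and 24 h in the authors' deposited table, all higher, with an adjusted p of 7.3e-29 at 6 h. It held 22, 35 and 27 with NT5M mRNA and 20, 30 and 25 with cdN mRNA, in the authors' deposited table, and 1 gene of the last was lower. The herpes simplex infection pathway of the authors' deposited table held 73 listed genes with CT mRNA at 12 h (adjusted p = 4.8e-29), 48 with NT5M mRNA and 32 with cdN mRNA. Zinc finger genes, which KEGG counts in that pathway, made up 57 of the genes higher with CT mRNA at 12 h, counted by symbol after the values were seen.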

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

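The tests on scaling, on reads taken by or amount of the transfected mRNA, and on RNA without poly(A) tails were chosen after the results were seen, as were the higher readthrough pairs and the count by gene pair, and the counts of splits and of lower readthrough pairs before. Genes named here that are not in the report were chosen after their values were seen. With time as a block, edgeR called 107 genes with a larger effect of CT than of cdN mRNA and 73 with a larger effect of CT than of NT5M mRNA, a difference between treatments under the same contrast. Genes listed with opposite signs for 2 of the mRNAs at 1 time numbered 8, among them PDCD6-AHRR, TSNAX-DISC1 and SETDB2-PHF11, and this difference was not tested. Genes listed with opposite signs at 2 times numbered 8 with CT, 10 with NT5M and 6 with cdN mRNA, among them RMRP, KLC3 and CNTF, which was not tested either. Splits of the 6 libraries of a pair of treatments number 10, too few for a share under 0.05. The real split called 139 genes for each mRNA against untransfected cells, 112 for CT against cdN, 104 for CT against NT5M and 105 for NT5M against cdN mRNA. In each case 1 split, the real one, called as many genes, and the highest other split called 0. For the contrasts with untransfected cells the choice of the 139 genes nearly fixed this outcome in advance, so it is no support. The other splits were also not held to 1 library of each time per group, so they are not like the real one.

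The larger folds of IFNB1, EGR4, PPP1R15A and most shared genes with CT mRNA could come from how the CT libraries were scaled, which as the whole cause would leave fewer genes lower with CT than with cdN mRNA. CT mRNA gave 2.74 times as many (126 against 46, exact 95% interval 1.94 to 3.93) at 12 h. At 24 h it gave 2.52 times as many (328 against 130, exact 95% interval 2.05 to 3.12). In these libraries both ratios argue against scaling as the whole cause at those times. At 6 h the ratio was 1.17 (49 against 42, exact 95% interval 0.757 to 1.81), which leaves scaling open at the time of the largest excess. The intervals count genes as independent, although the lists share a control and some genes. They hold no spread between libraries. Rescaling TPM without NT5C and NT5M left the median difference of CT and cdN mRNA at 12 h at 0.83 (quartiles 0.32 to 1.34), which argues against reads taken by the transfected mRNA. The transfected mRNA had a higher rpm in the cdN (218184) than in the NT5M library (165830) at 12 h. Folds were larger with NT5M mRNA by a median of 0.37 (quartiles 0.15 to 0.61), so amount did not order that pair at 12 h. The same held at 6 h (211028 against 164214 rpm, median 0.34). At 24 h the NT5M library had both the higher rpm (200344 against 175138 with cdN) and the larger folds (median 0.31). By share of TPM its transfected mRNA was lower there, at 24.97% against 33.4% with cdN mRNA. The order of amount at 24 h thus depends on the measure, and amount stays open there. The amount of CT mRNA was not measured here, and it stays open together with the encoded protein, the mRNA's sequence or purity and a difference between batches.

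Readthrough genes, which span a pair of neighbouring genes, made up 11 of 24 genes listed with both signs and 6.16% of lower against 0.916% of higher entries. Reads could be assigned to a readthrough gene in 1 library and to a spanned gene in another, which would give opposite signs. Where a lower readthrough gene and a gene it spans were listed together, 3 of 4 pairs (75%, exact 95% interval 19.4 to 99.4) had opposite signs, such as JMJD7-PLA2G4B and PLA2G4B with NT5M mRNA at 6 h. With a higher readthrough gene 8 of 8 did, and the 12 pairs came from 7 gene pairs, of which 6 (exact 95% interval 42.1 to 99.6%) had opposite signs throughout, which is in line with shared reads for these but too few to decide for the pattern. No biological explanation was tested.

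The replication-dependent histone mRNAs higher with CT mRNA lack poly(A) tails, so carry-over of such RNA into the libraries could raise them. The listed RNase P, RNase MRP, 7SK and 7SL RNAs were lower at 6 and 12 h instead, with a median log2 fold of -2.08 and a range of -7.53 to -1.84 over 6 values, which argues against it there. At 24 h they were higher, with a median of 2.13 and a range of 1.73 to 2.75, which goes with carry-over at that time. Of 24 listed ribosomal RNA copies 23 were higher too, but these copies are not separate observations. RNA5S1 and RNA5S2, for example, held the same counts (2 control and 32 CT reads). RNA28SN3 was 18.8-fold lower while RNA28SN1 was 6.38-fold higher. The median histone fold was 1.98, 2.85 and 2.88 on the log2 scale at 6, 12 and 24 h. Shifts of the other tail-less RNAs were not particular to CT mRNA. With cdN mRNA at 6 h RMRP, RPPH1 and RN7SK were 7.11-, 6.63- and 7.99-fold lower. With NT5M mRNA at 24 h RMRP and RPPH1 were 3.44- and 3.25-fold higher. None of these RNAs was listed with NT5M mRNA at 6 or 12 h or with cdN mRNA at 12 or 24 h. A change of histone mRNA processing or amount with CT mRNA stays open and untested.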

How the results depend on the processing

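The wider spread, the TPM scales, the set without readthrough and tail-less RNA genes, and the left-out times and 2-treatment fits of the contrasts between mRNAs and the CT time course at 6 and 12 h alone were chosen after seeing the data. Of 134 alternative values for 26 results, 92 stayed within the limits set (1.5 times for a count, the counting interval for the fold of a single gene) and 42 moved. A count could only be labelled as staying or moving, so a reversal could not be found for counts. Under an adjusted p of 0.05, 295, 600 and 580 genes counted for CT at 6, 12 and 24 h, 56, 320 and 252 for NT5M and 40, 212 and 149 for cdN mRNA. The count for all 3 mRNAs was then 31, 199 and 134, that of the CT time course 153, and that of list members over the 9 comparisons 446 in place of 967. Under a biological coefficient of variation of 0.6 the lists held 438, 756 and 771 genes for CT, 130, 486 and 393 for NT5M and 100, 322 and 286 for cdN mRNA. Both settings are stricter by construction. Counting coding genes alone gave 625, 1091 and 1157 for CT mRNA. A pseudocount of 1 gave 717 for NT5M at 24 h and 206 and 543 for cdN at 6 and 24 h, since it shrinks folds of genes with few reads. CT against cdN mRNA called 56 genes without 6 h, and CT against NT5M mRNA 12 without 6 h and 38 without 12 h. Without 24 h they called 102 and 52, and the cause of these differences was not tested. NT5M against cdN mRNA called 105 with only those libraries, and the cause was not tested. Against untransfected cells each mRNA called 139 genes without any 1 time, limma with a pseudocount of 5 called 139, 139 and 136 for CT, NT5M and cdN, and a level filter left 104 genes, all called. The choice of the 139 genes, listed in all 9 comparisons, nearly fixed these counts in advance, so they show no stability. Libraries of 1 time were matched only through the time block of the 139-gene fit. No paired analysis was possible because each group held 1 library at each time, other than that fit over the times. Genes with fewer than 10 control reads are limited by depth, as for CXCL11 with 1 control read at 24 h.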

Other observations

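The gene groups and tests of this part were chosen after the values were seen. Ribosome biogenesis genes of the KEGG pathway in the authors' deposited table were higher at 24 h for 26 genes with CT mRNA (adjusted p = 4.2e-13), 17 with NT5M mRNA (adjusted p = 9.2e-09) and 11 with cdN mRNA (adjusted p = 4.4e-05). At 12 h the authors' deposited table held 8 with CT mRNA, 7 of them higher (adjusted p = 0.047). Whether ribosomal RNA copies were counted in this pathway was not checked. At 24 h 23, 14 and 11 such copies were higher with CT, NT5M and cdN mRNA, and 1 was lower with CT mRNA. With CT mRNA at 12 h 2 were higher and 5 lower. Such copies are not separate observations. Zinc finger genes named ZNF, ZSCAN, ZKSCAN or ZFP were higher for 33, 57 and 31 genes with CT, 7, 31 and 14 with NT5M and 3, 19 and 9 with cdN mRNA at 6, 12 and 24 h. Those lower numbered 0, 0 and 5 with CT and 0, 1 and 1 with each of NT5M and cdN mRNA. All coding genes higher with CT mRNA numbered 605, 1009 and 866, and the share of zinc finger genes among all coding genes was not counted. Long noncoding RNAs higher numbered 241, 406 and 404 with CT mRNA, and those lower 19, 23 and 22.

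With CT mRNA at 24 h SCD, the stearoyl-CoA desaturase gene, was 4.73-fold (4.68 to 4.78) lower, FADS2, a fatty acid desaturase gene, 3.49-fold (3.42 to 3.56), FASN, the fatty acid synthase gene, 3.29-fold (3.20 to 3.37), and ACACA, an acetyl-CoA carboxylase gene, 3.48-fold (3.29 to 3.68). SREBF1, a transcription factor gene of lipid synthesis, was 3.77-fold (3.64 to 3.92) lower. SCD was 3.68-fold (3.66 to 3.71) lower with NT5M mRNA (adjusted p = 0.61 in the authors' deposited table) and was not listed with cdN mRNA. With CT mRNA the adjusted p in the authors' deposited table was 0.19 for SCD, 0.43 for FADS2, 0.49 for FASN, 0.43 for ACACA and 0.36 for SREBF1, so each fails that correction, and the genes were not tested as a group. Collagen genes went both ways with CT mRNA at 24 h, COL1A2 3.84-fold (3.74 to 3.95) and COL3A1 4.71-fold (4.52 to 4.91) lower, COL7A1 7.65-fold (6.96 to 8.42) and COL5A3 38.2-fold (19.4 to 85.8) higher. Their adjusted p in the authors' deposited table was 0.34, 0.19, 0.039 and 2.0e-04 in turn.

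In untransfected cells IFIT2 stood at 69.1, 54.1 and 142 rpm at 6, 12 and 24 h. With CT mRNA its level was 9641, 11248 and 4959.8 rpm. Ribosomal RNA copies were listed in both directions, with 2 higher and 5 lower with CT mRNA at 12 h, 3 lower with cdN mRNA at 6 h and 14 and 11 higher with NT5M and cdN mRNA at 24 h.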
